A study of Brassica rapa with 5 samples.

How the data were processed

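Small RNA was sequenced from anthers of Brassica rapa, with 3 libraries of the wild type line R-o-18 and 2 of the mutant rdr2-2. RDR2 is an RNA-dependent RNA polymerase that copies transcripts of RNA polymerase IV into double strands, which are cut into 24-nt small interfering RNAs (siRNAs). Per the labels' protocols, total RNA was extracted with TRIzol, size-selected and made into libraries with the Illumina TruSeq small RNA kit, and the libraries were sequenced on a HiSeq instrument. The labels name the replicates by number and do not say whether they came from separate plants, so the p-values measure only the spread between these samples, which may be technical.

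The deposited files list distinct sequence tags with raw read counts, 1 file per library. Per the submitters' processing notes, reads were trimmed with Trimmomatic; its version and the other steps are not given in the sources used here. The tags were between 18 and 34 nt long, and tags seen once were present, so no minimum count had been applied. No read counts were normalised by the authors in these files, and the tags carried no gene names or positions.

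Tags of 18 to 30 nt were used. Their totals were 20673141, 5619740 and 11298521 reads in wild type replicates 1, 2 and 3 and 8568258 and 4785826 reads in rdr2 replicates 1 and 2. These totals were the library sizes for every level in rpm. At these depths the 95% exact (Clopper-Pearson) interval of a 24-nt share was at most 0.0261 percentage points to either side. The floor of 3 reads corresponded to 0.145 to 0.627 rpm in a single library. Reads were PCR products without molecular identifiers, so intervals and floors cover counting error only. Between 1.43% and 1.55% of these reads held an uncalled base; they stayed in the totals and were left out of the tests. Replicates were compared before they were averaged. Chi-square values per degree of freedom between replicates ranged from 23.8 to 89.0, so that no pair agreed within sampling noise, and each library was counted as 1 replicate.

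No genome was used. Listed sequences were matched to the tags exactly over their whole length. The list held 64 plant miRNAs and 3 trans-acting siRNAs (tasiRNAs), written before the data were examined, as were the 5 tRNA 5′ ends, the designs and the alternative settings. The listed miRNAs fell into groups for development, Brassicaceae-specific families, the silencing machinery, tasiRNA triggers, nutrient response, NLR resistance genes, pollen, and triggers of phased siRNAs in grass anthers. A list of 7 rRNA sequences of the cytosol, plastid and mitochondrion was written from general knowledge after the tags had been seen, and reads matching any part of them without mismatch were counted. Also chosen after seeing the data was a class of tags that needs no genome. A tag of 18 to 25 nt was called contained when it lay inside a tag of 26 to 30 nt that had at least 2 reads over the 5 libraries, since such tags can be pieces of longer RNA. All other tags of 18 to 25 nt were called not contained in longer tags, and each tag kept its class in every library. Windows of the genome, siRNAs in annotated genes, annotation classes and phased loci had been planned, need a genome, and were not analysed here. Transcripts of RDR2, the DCL genes and the AGO genes were not measured, so the genotype of a library was not checked on the mutated gene itself.

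Shares of reads were compared with an exact permutation test of the difference of means, two-sided, over all 10 splits of the 5 libraries; the smallest p it can give is 0.2, so none could reach 0.05. By chance 20% of measures would have groups that do not overlap. Benjamini-Hochberg values were computed within each family of measures. Tags and miRNAs were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with robust estimation, on tags with at least 10 reads in at least 2 libraries, with the library sizes above and no further factor, and Benjamini-Hochberg adjustment at 0.05. For miRNAs the adjustment was made over all tags and over the list alone. The design also named a test relative to the sum of the listed miRNAs. The form used here, the same test on the listed miRNAs alone with the sum of their reads as library size, was chosen later, as were the sum of listed miRNA reads as a measure and the first base at 21 nt without listed miRNAs. Groups of miRNAs were tested in that fit with camera (preset correlation 0.01, then estimated) and fry (limma 3.58.1). The edgeR step was tested on simulated data for the comparison of rdr2 with wild type over 73474 tags, of which 200 were changed. Of 50 tags each, it recovered 86.0% of those raised by 4 on the log2 scale and 22.0% of those lowered by 4, 4.00% of those raised by 2 and 2.00% of those lowered by 2. It made 5 false calls among 62, and the median estimates were 4.05, -4.25, 2.05 and -2.12. In the data far more tags passed (3260 rose and 13184 fell), and the miRNAs were also adjusted over the list alone. Both change the cut-off, so these rates do not give the power of the tests reported.

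Alternative settings fixed with the design were TMM factors, DESeq2 1.42.0, library sizes set to the listed miRNA reads, a filter of 5 reads over all libraries, the replicate number as a block, matching of miRNAs by their first 18 bases, other denominators and distinct tags for the shares, and leaving out each library. The miRNAs named are the 5 most abundant in the wild type, the 10 with the largest change past the threshold over the list without overlap between genotypes, and up to 4 of the most abundant of each group. The tags named are the 5 most abundant that rose and the 5 most abundant that fell. Shares and intervals were computed with Python 3.11.15 and scipy 1.17.1.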

Results

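Small RNA of anthers was compared between wild type plants of the Brassica rapa line R-o-18 (n = 3) and plants of the same species that carry the mutation rdr2-2 (n = 2). The files held 23995695, 6638285 and 12958661 reads for wild type replicates 1, 2 and 3, and 10340963 and 6218989 reads for rdr2 replicates 1 and 2. Of these, 4785826 to 20673141 reads per library were 18 to 30 nt long, and levels are given in rpm of these reads. RDR2 makes the double-stranded precursors of 24-nt siRNAs, which guide DNA methylation to transposons and repeats, so the first comparison asked which size classes differed between the genotypes.

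Reads of 24 nt were less abundant in rdr2 anthers. They made up 11.5% ± 0.771 of all 18-30 nt reads in the wild type (SD, n = 3) and 7.04% ± 1.32 in rdr2 (SD, n = 2). Much of what remained at 24 nt lay inside longer tags. So did most reads of 18 to 25 nt in both genotypes. Of these, 16.4% ± 2.16 in the wild type and 12.8% ± 3.27 in rdr2 were not contained, with overlap. The class of contained tags is no proof of breakdown. The abundant tags of miR166a, miR165a, miR398b and miR408 fell into it too, so a true small RNA can be classed as contained. The 24-nt reads that were not contained in longer tags made up 4.29% ± 0.877 of all reads in the wild type and 1.04% ± 0.154 in rdr2, which was 4.11-fold lower. Counted against the miRNAs of the same library, whose summed level was itself 4.44-fold higher in rdr2, these 24-nt reads were 14.6-fold lower. They stood at 170.8 ± 25.1 per 100 listed miRNA reads in the wild type and 11.7 ± 6.90 in rdr2. The rdr2 libraries stood apart here, at 16.6 in replicate 1 and 6.81 in replicate 2, and without replicate 1 the log2 ratio moved from -3.87 to -4.65. In each of these measures the rdr2 libraries lay outside the range of the wild type libraries, and the exact permutation test gave the smallest p this design allows (p = 0.2, two-sided). The adjusted p of the exact permutation test was 0.267 for the 24-nt share over 4 lengths, 0.4 for the 24-nt reads not contained in longer tags over 4 lengths, and 0.333 for the ratio to miRNAs over 5 measures.

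Reads of 21 nt, the usual size of miRNAs, made up 14.2% ± 1.70 in the wild type and 25.3% ± 11.5 in rdr2, without overlap (exact permutation p = 0.2). The 2 rdr2 libraries stood far apart here, at 17.1% in replicate 1 and 33.4% in replicate 2, so the size of the difference rests on replicate 2. Reads of 22 nt were at 11.6% ± 1.21 in the wild type and 13.3% ± 1.91 in rdr2, with overlapping groups (exact permutation p = 0.4). Reads of 23 nt were at 8.87% ± 0.166 and 7.60% ± 1.19 (exact permutation p = 0.2). Their difference moved from -1.27 percentage points to -0.43 without rdr2 replicate 2 and to -2.11 without rdr2 replicate 1.

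**Figure D1:**
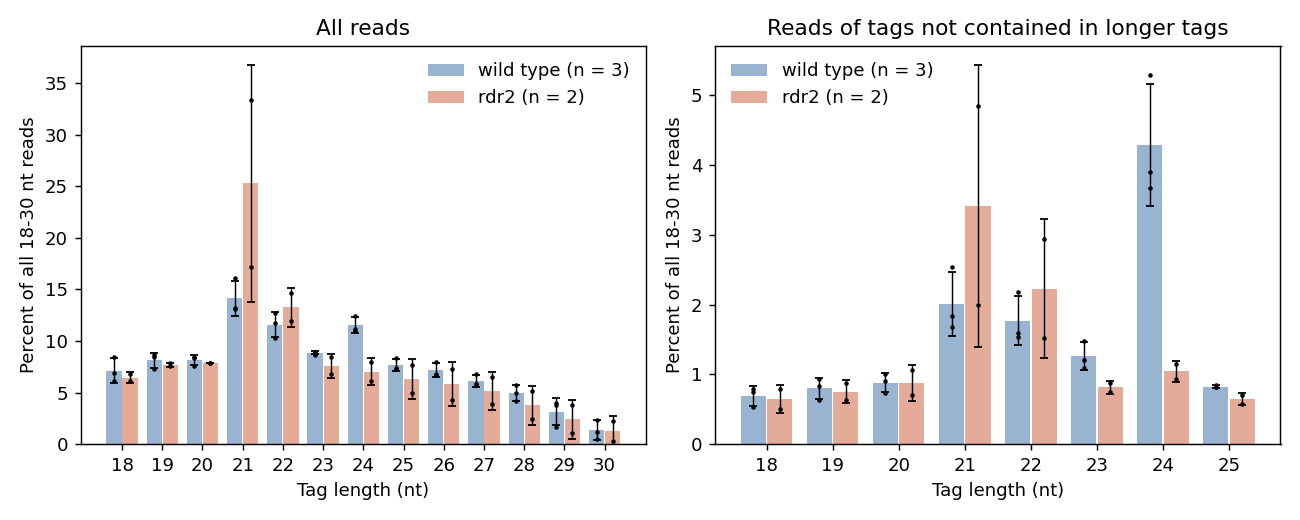
Share of each tag length from 18 to 30 nt among all 18-30 nt reads, in percent, for all reads and for reads of tags not contained in longer tags; bars are means, error bars are SD and points are the single libraries (3 wild type, 2 rdr2). At 24 nt the tags not contained in longer tags stood at 4.29% in the wild type and 1.04% in rdr2.

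The first base of the 24-nt reads also differed. An adenine at the first position, the base known to be favoured by the Argonautes that bind 24-nt siRNAs, was found in 38.8% ± 0.755 of the wild type 24-nt reads and in 26.02% ± 0.563 of those of rdr2. Cytosine was higher in rdr2, at 30.4% ± 0.118 against 24.5% ± 0.378, and so was guanine, at 25.1% ± 0.344 against 19.0% ± 0.198. Thymine was at 18.6% ± 0.101 in rdr2 and 17.7% ± 0.382 in the wild type. Among 24-nt reads not contained in longer tags, the share with adenine was 57.9% ± 1.74 in the wild type and 32.7% ± 2.25 in rdr2. For each of the 4 bases at 24 nt the genotypes did not overlap (exact permutation p = 0.2, adjusted p = 0.289 over 13 shares). The 4 shares together make up all 24-nt reads, so a lower share of adenine raises the others. They are thus not separate results.

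At 21 nt, thymine, which stands for the uracil at the start of most miRNAs, was the first base of 38.5% ± 2.14 of the wild type reads and 56.5% ± 12.5 of the rdr2 reads. Adenine, cytosine and guanine at 21 nt were lower in rdr2, at 14.3% ± 2.67, 20.7% ± 6.78 and 8.47% ± 3.01 against 18.1% ± 1.51, 30.7% ± 1.36 and 12.7% ± 0.791. Once the listed miRNAs were left out, thymine at 21 nt was at 25.9% ± 0.855 and 29.3% ± 7.19, with overlap between genotypes. Without rdr2 replicate 2 the differences at 21 nt shrank, from 18.03 to 9.23 percentage points for thymine, from -3.80 to -1.92 for adenine, from -10.03 to -5.23 for cytosine and from -4.20 to -2.08 for guanine. In distinct tags, thymine at 21 nt was lower in rdr2 by 1.70 percentage points. Cytosine and guanine also turned there, higher by 2.23 and 0.393, while adenine stayed lower, by 0.930. At 22 nt, thymine stood at 28.3% ± 2.29 and 25.04% ± 1.01, adenine at 20.2% ± 1.70 and 17.1% ± 2.09, and cytosine at 23.4% ± 2.48 and 20.6% ± 0.0938 in the wild type and rdr2, each with overlap. Guanine at 22 nt was at 28.1% ± 5.49 and 37.2% ± 0.988. Without tags that resemble the sequencing adapter it was at 21.7% ± 2.42 and 24.4% ± 2.12.

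The second comparison asked which single sequences differed. Among the tag classes of each length, the 24-nt tags not contained in longer tags had the largest share of losses. Of 2193 such tags tested, 1465 (66.8%) fell in rdr2 and 59 rose. In 1581 of them (72.1%) both rdr2 libraries had 0 reads. With such tags set to the floor of 3 reads over the 2 rdr2 libraries, the median tag was at least 4.74-fold lower in rdr2. A tag absent from rdr2 could pass the read filter in any 2 of the 3 wild type libraries. A tag absent from the wild type had to pass it in both rdr2 libraries. The split of falls and rises and the share with 0 rdr2 reads thus depend in part on filter and depth. With the filter of 5 reads over all libraries, 1956 of 33440 24-nt tags not contained in longer tags fell and 193 rose. Among the 2193 tags, losses were frequent in those with adenine first, with 1188 of 1625 fallen. The counts were 111 of 227 with cytosine, 68 of 159 with guanine and 98 of 182 with thymine. The 24-nt tags contained in longer tags were less affected in number, with 952 of 7461 fallen and 106 risen. Of 4550 tags of 21 and 22 nt not contained in longer tags, 997 rose and 1062 fell. The other lengths of that class did not split so evenly. At 18 nt 196 of 508 fell and 33 rose, at 19 nt 193 of 589 and 41, and at 20 nt 158 of 571 and 58. At 23 nt 101 of 431 fell and 32 rose, and at 25 nt 8 of 72 and 5.

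Examples of 24-nt tags from the depleted class illustrate the size of the loss; they were chosen after their values were seen, as the most abundant of those that fell. The tag AAAACAACACTAAAGATTATAGGC stood at 69.5 ± 17.96 rpm in the wild type and 1.07 ± 0.852 in rdr2 (log2 fold change -6.11, SE 0.69, edgeR adjusted p = 0.00029). AGGAGTTGGGATGAAGAAGTTATC fell from 45.2 ± 12.0 to 1.85 ± 0.847 rpm, and GATAACTCTGGTATCTGGGCAGCC from 38.1 ± 8.22 to 0.292 ± 0.413.

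Over all 90700 tags tested, 3260 rose and 13184 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). With library sizes set to the listed miRNA reads the split was 218 and 23869. It was 2273 and 7727 with TMM factors and 3678 and 9763 with DESeq2. The most abundant tags that rose were those of miR166a, miR165a, miR398b and miR408 and a 22-nt tag of no listed name, AGTTACTAATTCATGATCTGGC, at 712 ± 122 rpm in the wild type and 2110 ± 1037 in rdr2. The most abundant tags that fell bore no listed name, and none was a 24-nt tag of the depleted class. Their origin was not analysed here, and pieces of organelle RNA were not excluded, so their loss is not tied to siRNAs made with RDR2. GCATTGAGAAGGAAGGACG (19 nt) had the largest change of these, from 766 ± 175 to 4.81 ± 0.298 rpm (log2 fold change -7.31, SE 0.59, edgeR adjusted p = 0.000143). TTGAAGAGAGCTCTAACAGG fell from 796 ± 361 to 33.3 ± 10.2, TTTCTTTTCAGGCTTGACT from 475 ± 189 to 22.2 ± 7.08, ACTATAATGAGGAGGACGACTGACCC from 610 ± 131 to 94.6 ± 20.1, and GCGTCTGTAGTCCAACGGTTAGGA from 760 ± 217 to 282 ± 41.9 rpm. The call of the last of these tags was lost with TMM factors, with DESeq2 and with the replicate number as a block. The counts of tags that rose and fell depend on single libraries. Without rdr2 replicate 2, 351 tags rose and 3271 fell, 337 of them 24-nt tags not contained in longer tags; without rdr2 replicate 1, 2881 fell, 232 of them in that class, and without wild type replicate 1, 1925 rose and 909 tags of that class fell.

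The third comparison concerned conserved miRNAs, which are made without RDR2. In rpm, the listed miRNAs together stood at 25389 ± 5594 in the wild type and 112772 ± 79748 in rdr2, with 56382 in replicate 1 and 169162 in replicate 2 (exact permutation p = 0.2). Of 37 miRNAs with enough reads to test, 13 rose and 0 fell in the edgeR test adjusted over the list alone, and 10 rose and 0 fell when adjusted over all tags. At an unadjusted p below 0.05, 18 rose and 0 fell, and DESeq2 gave 16 and 0 over the list. The genotypes did not overlap for 18 of the 37 miRNAs (48.6%), 17 of them higher in rdr2. By chance 20% would not overlap, but the miRNAs of a library share its summed miRNA level and can separate together. The 48.6% is therefore no evidence beyond the difference in that sum. Without rdr2 replicate 2, the log2 ratio of the summed reads moved from 2.15 to 1.15 and 6 miRNAs rose, and without wild type replicate 3, 21 rose. With counts scaled to the listed miRNA reads none rose, and because 32 of the 37 were higher in rpm and 5 lower, each group below is also described relative to the sum of the listed miRNAs.

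Relative to their own sum, 4 miRNAs rose and 13 fell in the fit of the listed miRNAs alone (edgeR, adjusted over the list alone), which was chosen after the data were seen. In the fit of all tags at the same scale, 0 rose and 0 fell when adjusted over the list alone, and 3 fell and 0 rose over all tags; the fold changes were nearly the same (1.84 for miR157a and -3.48 for miR158a in both). The SE there was larger, at 0.98 against 0.35 for miR157a and 1.14 against 0.46 for miR158a. Each SE was computed from the fold change and the F statistic of the edgeR test. Its size therefore restates the absence of calls and does not explain it. The calls relative to the sum given below are those of the fit of the listed miRNAs alone. The members of miR165 and miR166, which target class III HD-ZIP transcription factors of organ polarity, held 75.5% ± 5.33 of the listed miRNA reads in the wild type and 75.5% ± 4.59 in rdr2, and so set this scale. On it 31 of the 37 miRNAs tested were lower in rdr2 and 6 higher. The median log2 fold change was -0.78, and -0.14 with TMM factors within the list. With TMM factors within the list, 5 rose and 6 fell, and without rdr2 replicate 2, 2 rose and 6 fell.

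In the developmental group, 8 of 20 tested members rose in rpm over the list alone and 0 fell. miR166a rose from 15419 ± 3329 to 65218 ± 43173 rpm (log2 fold change 2.08, SE 0.50, edgeR adjusted p = 0.00477), and miR165a from 3707 ± 786 to 18079 ± 11853 (2.29, SE 0.49). miR157a, a repressor of SPL transcription factors of phase change, had the largest change of all, from 24.9 ± 5.35 to 392 ± 272 rpm (log2 fold change 3.98, SE 0.51, edgeR adjusted p = 8.38e-05). miR156a of the same family, named after its values were seen, was at 128 ± 40.1 and 134 ± 103 (log2 fold change 0.06, SE 0.52). Counted by its first 18 bases, miR156a rose by 1.37 on the log2 scale (edgeR adjusted p = 0.0425), so that its level depends on which forms are counted. miR167d, which targets the auxin response factors ARF6 and ARF8 needed in anthers, rose by 3.28 on the log2 scale (SE 0.56), miR396b, a regulator of GRF growth factors, by 1.91 (SE 0.46), and miR319a, a regulator of TCP factors, by 1.72 (SE 0.47). miR159a, which targets GAMYB-like factors of the anther, was at 227 ± 66.0 and 367 ± 71.7 rpm, and miR393a, which targets auxin receptors, at 144 ± 91.0 and 195 ± 134; neither passed the test. Without rdr2 replicate 2 the log2 fold changes in rpm were 3.01 for miR157a, 2.35 for miR167d, 1.39 for miR165a, 1.19 for miR396b, 1.17 for miR166a and 0.93 for miR319a, and the last 3 did not pass the test. Relative to the sum, 2 members of this group rose, miR157a (log2 fold change 1.84, SE 0.35) and miR167d (1.18, SE 0.33), and 5 fell, among them miR156a (-2.11, SE 0.38). The call of miR167d rests on both rdr2 libraries, with an edgeR adjusted p of 0.0862 without replicate 1 and 0.0792 without replicate 2.

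The nutrient group held 3 members that rose among 6 tested. Low copper is known to induce all 3, a feature noted after the result and not tested as a group. miR408, which targets blue copper proteins and laccases, rose from 391 ± 144 to 4572 ± 3374 rpm (log2 fold change 3.55, SE 0.54, edgeR adjusted p = 0.000369). miR398b, which targets copper/zinc superoxide dismutases, went from 1593 ± 849 to 17527 ± 16395 (3.46, SE 0.69, adjusted p = 0.00358 by edgeR) and miR397a, which targets laccases, from 14.4 ± 6.32 to 116 ± 82.6 (3.00, SE 0.55). The log2 fold changes were 2.48 for miR408, 1.90 for miR398b and 1.99 for miR397a without rdr2 replicate 2. These 3 miRNAs also stood higher relative to the sum, by 1.41 (SE 0.26) for miR408, 0.83 (SE 0.33) for miR397a and 1.18 (SE 0.42) for miR398b on the log2 scale. The first 2 passed the edgeR test there, and miR398b did not (adjusted p = 0.0772). Both outcomes depend on the setting. miR397a lost its call without wild type replicate 3 (edgeR adjusted p = 0.0679), rdr2 replicate 1 (0.222) or rdr2 replicate 2 (0.278). miR398b passed the edgeR test with TMM factors (adjusted p = 0.000355), without wild type replicate 3 (3.06e-05) and without rdr2 replicate 1 (6.45e-05). The sulfate-linked miR395a was at 19.6 ± 4.91 and 26.5 ± 16.3 rpm and did not rise.

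In the silencing group, which targets the small RNA machinery itself, 2 of 4 members rose in rpm. They were miR403, which targets AGO2, from 789 ± 190 to 2012 ± 1451 rpm (log2 fold change 1.35, SE 0.49), and the Brassica form of miR168, which targets AGO1, from 95.8 ± 5.81 to 277 ± 170 (1.53, SE 0.45). Their adjusted p over the list alone was 0.0441 and 0.0163 in edgeR. Both lost their call without wild type replicate 1 and with the replicate number as a block, and miR403 also without wild type replicate 2. They stood at 0.32 and 0.72 on the log2 scale without rdr2 replicate 2 and did not pass there. miR162a, which targets DCL1, was at 86.7 ± 56.6 and 156 ± 100.5, and miR168a at 35.1 ± 4.44 and 59.9 ± 33.5. Relative to the sum 3 of the 4 fell and none rose, among the fallen miR403 (-0.82, SE 0.27), whose edgeR call was lost with TMM factors (adjusted p = 0.858), without either rdr2 library (0.136 and 0.163) and without wild type replicate 3 (0.0536). The fry test gave a shift down for this group (adjusted p = 0.0212, limma), and camera did not set it apart from the other listed miRNAs (adjusted p = 0.468, and adjusted p = 0.650 with an estimated correlation). The fry test compares with no change on a scale where 31 of the 37 miRNAs were lower. Its result is thus not particular to this group.

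The Brassicaceae-specific group had 0 of 4 members past the edgeR threshold in rpm, 0 at an unadjusted p below 0.05 and 0 with DESeq2. The Brassica form of miR158 was at 1997 ± 652 and 2349 ± 1753 rpm, miR158a at 225 ± 93.7 and 92.4 ± 77.6, miR400 at 1.12 ± 0.361 and 2.73 ± 2.05, and miR824 at means of 0.451 and 1.71. Relative to the sum, both forms of miR158 fell, by 1.95 (SE 0.23) and 3.48 (SE 0.46) on the log2 scale. The group shifted down in the fry test (adjusted p = 0.0212, limma) and did not stand apart in camera (adjusted p = 0.294, and adjusted p = 0.650 with an estimated correlation). This fry result, too, was obtained on the scale where most listed miRNAs were lower. Camera gave an adjusted p of 0.251 for the nutrient group and 0.468 for the developmental group, each 0.650 with an estimated correlation. The fry test of a shift in 1 direction gave an adjusted p of 0.543 for the nutrient group and 0.162 for the developmental group (limma). Its test of changes in either direction gave an unadjusted p of 0.000868 for the nutrient, 0.00295 for the developmental, 0.00504 for the silencing and 0.000983 for the Brassicaceae-specific group.

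miR1885a, a Brassica miRNA directed at NLR resistance genes, was at 91.2 ± 47.4 and 56.9 ± 39.5 rpm, and fell relative to the sum (log2 fold change -2.80, SE 0.40). The tasiRNA trigger miR390a was at 35.9 ± 18.3 and 101 ± 73.3 rpm and passed the test in neither fit (edgeR adjusted p = 0.0523 in rpm). It passed in rpm when counted by its first 18 bases (edgeR adjusted p = 0.0473) and with DESeq2 (0.0349). Its product tasiARF-D7 was near the floor in both genotypes, at 0.497 ± 0.260 and 0.848 ± 0.869 rpm. Of 67 listed sequences, 20 had 0 reads in all 5 libraries. These included miR173, miR2118 and miR2275, the last 2 being triggers of phased siRNAs in grass anthers, and 0 reads allowed up to 0.0798 rpm in the wild type and 0.225 in rdr2, each over its pooled libraries.

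**Figure D2:**
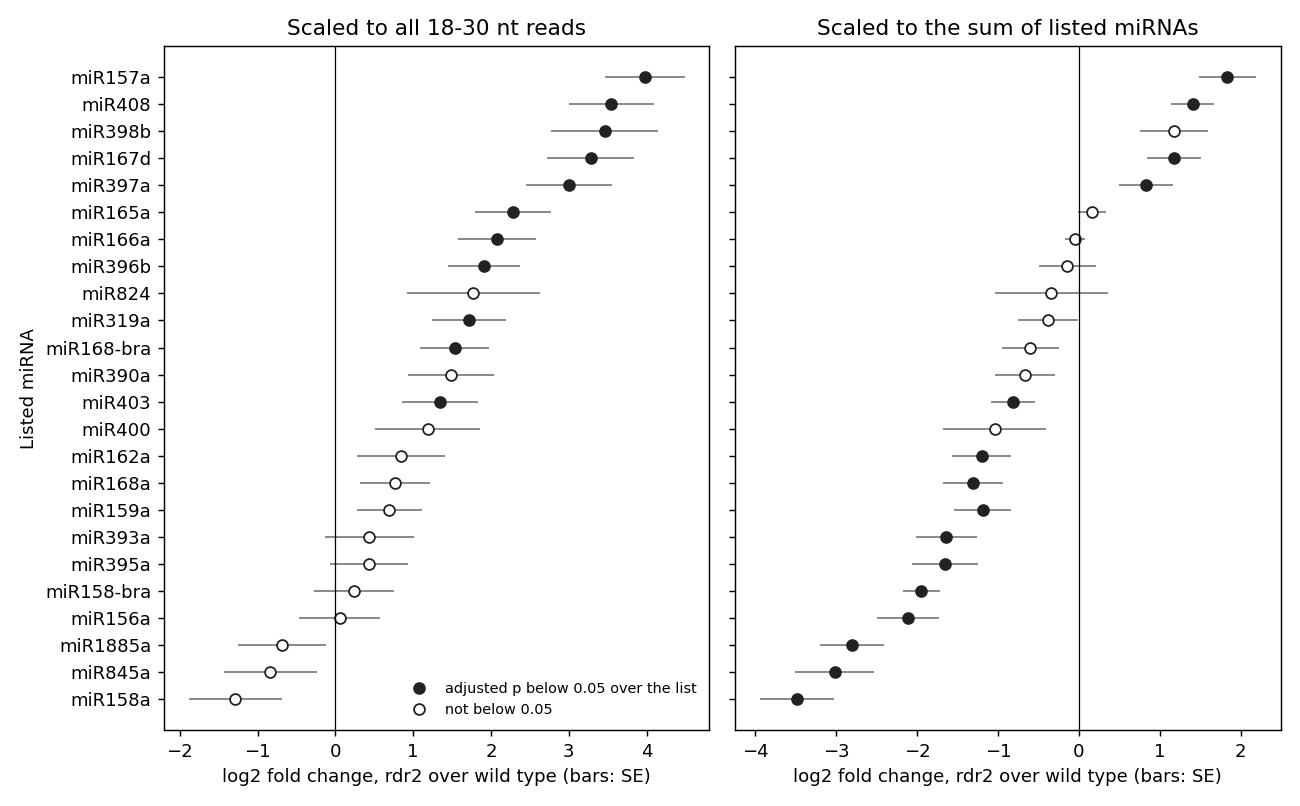
Log2 fold change of rdr2 over wild type for the 24 miRNAs named here, scaled to all 18-30 nt reads and to the sum of the listed miRNAs; bars are standard errors and filled points have an edgeR adjusted p below 0.05 over the list. miR157a, miR408, miR398b, miR167d and miR397a lie highest on both scales, while miR158a, miR845a and miR1885a lie lowest.

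Markers of pollen and signs of RNA quality were measured in the same libraries. The pollen miRNA miR845a, which targets primer binding sites of LTR retrotransposons, was at 14.9 ± 5.39 rpm in the wild type and 8.45 ± 6.67 in rdr2, did not pass the test in rpm, and fell relative to the sum (log2 fold change -3.02, SE 0.49). miR845b had 0 reads. Fragments of the tRNA-Ala 5′ end, abundant in pollen, were at 1775 ± 245 and 2036 ± 133 rpm, with overlap (exact permutation p = 0.4). The 5 tRNAs together gave 2528 ± 364 and 2954 ± 156. Those of tRNA-Gly stood at 436 ± 128 and 565 ± 317 and those of the initiator tRNA-Met at 273 ± 31.0 and 252 ± 87.0. Fragments of tRNA-Asp were higher in rdr2, at 100.5 ± 59.4 against 22.8 ± 7.42 rpm, without overlap (exact permutation p = 0.2, adjusted p = 0.8 over 6 measures), and without rdr2 replicate 2 the log2 ratio moved from 2.14 to 1.36. tRNA-Glu fragments were at 62.9 rpm in wild type replicate 1 and at most 0.836 elsewhere.

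Fragments of cytosolic rRNA were at 43038 ± 10102 rpm in the wild type and 41444 ± 17081 in rdr2, and those of plastid rRNA, a sign of green tissue, at 12448 ± 4852 and 15372 ± 2555, both with overlap. Fragments of mitochondrial rRNA were lower in rdr2, at 335 ± 108 rpm against 1358 ± 391, or 4.05-fold, without overlap (exact permutation p = 0.2, adjusted p = 0.7 over 14 measures). Fragments of 18 to 24 nt were at 993 ± 351 and 178 ± 7.94 rpm, 5.57-fold lower without overlap, while those of 28 to 30 nt were at 93.7 ± 31.5 and 57.0 ± 52.8, with overlap (exact permutation p = 0.6).

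**Figure D3:**
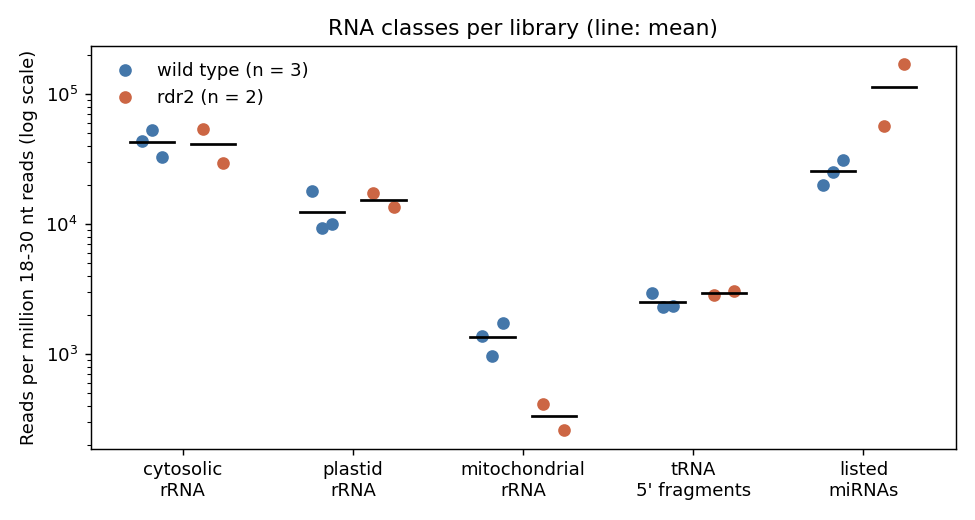
Levels in rpm, on a log scale, of fragments of the listed rRNAs by compartment, of tRNA 5′ fragments and of listed miRNAs. Each point is a library (3 wild type, 2 rdr2) and each line a mean. The mitochondrial rRNA fragments and the miRNAs separate the genotypes, at means of 1358 and 335 and of 25389 and 112772 rpm.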

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

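Tags of 34 nt, the longest in the files, lay outside the measured range of 18 to 30 nt and were more frequent in both rdr2 libraries than in any wild type library. They made up 15.3% of all reads in rdr2 replicate 1 and 22.7% in replicate 2, against 12.6%, 14.9% and 12.5% in wild type replicates 1, 2 and 3. The share of these 34-nt reads that held sequence of the library adapter was 24.4% and 51.6% in rdr2 and 14.2%, 24.5% and 16.9% in the wild type. The 34-nt reads without it made up between 10.4% and 11.6% of all reads in each of the 5 libraries.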

How the results depend on the processing

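Leaving out adapter-like tags, every result on tags contained in longer tags, the rRNA results, the fit of miRNAs relative to their sum with all its settings, the sum of listed miRNA reads and thymine at 21 nt without listed miRNAs were chosen after the data were seen. The remaining settings were set beforehand. Of 321 recomputed values of shares, levels and counts, 278 kept their direction or size; of 288 for the named miRNAs in rpm 234 kept direction and side of the threshold, as did 54 of 66 relative to the sum and 134 of 150 for named tags. The lower 24-nt share and the lower share of adenine at 24 nt kept their direction in each alternative run, and so did the lower mitochondrial rRNA without each library. The placement of reads in a genome, shares without structural RNA so placed, and all results of windows, genes, annotation classes and phased loci were not run. The depth of rdr2 replicate 2, 4785826 reads, limits the smallest level that can be seen to 0.627 rpm there.

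Scaling moved the counts, and so did leaving out a library. The reported fit put the median tag at -0.36 on the log2 scale, TMM at -0.19, DESeq2 at -0.18 and the miRNA scaling at -2.01. TMM factors gave 7727 tags that fell, 876 of them 24-nt tags not contained in longer tags. With library sizes set to the listed miRNA reads, 218 tags rose and 23869 fell, and 0 miRNAs rose; this follows from the scale, which the miRNAs themselves set. That scaling turned these named sequences to lower values in rdr2: miR156a -2.11, miR158-bra -1.95, miR159a -1.19, miR162a -1.20, miR166a -0.0436, miR168a -1.31, miR168-bra -0.60, miR319a -0.38, miR390a -0.66, miR393a -1.63, miR395a -1.65, miR396b -0.14, miR400 -0.98, miR403 -0.82, miR824 -0.29 and the 22-nt tag -0.48. With the filter of 5 reads over all libraries, 6951 tags rose and 1 miRNA fell, among more tags tested. Within the listed miRNAs, TMM factors left 6 that fell. Matching by the first 18 bases turned the Brassica form of miR158 to -0.21 and brought miR156a (1.37, edgeR adjusted p = 0.0425) and miR390a (0.0473) past the threshold. miR168a and the Brassica form of miR168 share these bases, so their pooled count (1.35, 0.0320) adds no separate call. For the first base, counting distinct tags turned thymine (-1.70 percentage points), cytosine (2.23) and guanine (0.393) at 21 nt and cytosine at 22 nt (2.61), and leaving out tags contained in longer tags turned adenine (0.162) and cytosine (0.0936) at 22 nt. The cause was not tested.

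Replicate numbers were shared by the genotypes for 2 pairs, and nothing in the labels ties them to a shared day or plant. With the replicate number as a block, 1926 tags rose and 7965 fell, 814 of them 24-nt tags not contained in longer tags, and 7 miRNAs rose. The calls of miR168-bra (edgeR adjusted p = 0.127), miR319a (0.0955), miR396b (0.0567) and miR403 (0.127) were lost, as were those of the 22-nt tag (0.202) and GCGTCTGTAGTCCAACGGTTAGGA (0.375). The fold changes of these miRNAs stayed near the reported ones, at 1.42, 1.79, 1.91 and 1.35 on the log2 scale, while the SE grew to between 0.73 and 0.80. The deviations of same-numbered samples correlated at 0.302 and -0.338 across tags.

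Leaving out 1 library left that genotype with fewer samples, and with 1 rdr2 library that sample is assumed to vary like the wild type. Over the 5 libraries left out in turn, tags that rose ranged from 351 to 3805 and those that fell from 2881 to 17424, 24-nt tags not contained in longer tags that fell from 232 to 1858, miRNAs that rose from 6 to 21 and that fell from 0 to 1, and relative to the sum those that rose from 2 to 4 and that fell from 6 to 19. Without rdr2 replicate 2 several values changed sign. Their ranges were -0.0236 to 2.83 percentage points for 21-nt and -0.249 to 1.17 for 22-nt reads not contained in longer tags, and -1.66 to 8.51 for thymine at 21 nt without listed miRNAs. On the log2 scale the ranges were -0.36 to 0.85 for tRNA-Gly, -0.52 to 0.20 for the initiator tRNA-Met, -0.55 to 0.31 for cytosolic rRNA (also turned without wild type replicate 2) and -2.25 to 0.00985 for mitochondrial fragments of 28 to 30 nt. They were -1.08 to 0.69 for miR156a (also turned without wild type replicate 1), -0.85 to 0.85 for miR158-bra, -0.0356 to 1.53 for miR162a, -0.52 to 1.09 for miR393a and -0.39 to 0.96 for miR395a. tRNA-Glu ranged from -7.50 to 1.84 and turned without wild type replicate 1. The calls of miR166a, miR168-bra, miR319a, miR396b and miR403 in rpm were lost without rdr2 replicate 2. Without wild type replicate 1 miR168-bra (edgeR adjusted p = 0.0529) and miR403 (0.106) were lost, and without wild type replicate 2 miR403 (0.117). The 22-nt tag lost its call without wild type replicate 1 (0.0915), wild type replicate 3 (0.0610) or rdr2 replicate 2 (0.182). With libraries left out in turn, GCGTCTGTAGTCCAACGGTTAGGA kept its call only without wild type replicate 2, and it lost it with TMM factors (0.0672) and DESeq2 (0.0599). Calls gained were miR162a, miR390a and miR824 without wild type replicate 3, miR168a, miR390a, miR400 and miR824 without rdr2 replicate 1, and a fall of miR158a without rdr2 replicate 2 (0.0242). With the filter of 5 reads over all libraries, miR158a (0.0122) and miR390a (0.00400) also passed.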

Other observations

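The tests below were chosen after the results were seen, except the comparison of windows along the mitochondrial rRNAs, which was written down before its values were computed.

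A few 24-nt tags not contained in longer tags went against the class and rose in rdr2; the 3 most abundant are named here after their values were seen. TGCACTGCCTCTTCCCTGGCTCCC shares 20 bases with miR408, starts 1 base later and runs 4 bases further at its 3′ end. It rose from 35.0 ± 13.8 to 282 ± 199 rpm (log2 fold change 3.01, SE 0.52), beside miR408 itself at 3.55. ATCGAATCTTAGCGACAAAGGGCT was at 17.2 ± 8.56 and 92.6 ± 35.2 rpm. Without rdr2 replicate 2 the calls of these first 2 tags were lost (edgeR adjusted p = 0.0509 and 0.0913). ACACAGGAACAATACTAACTCATT was nearly restricted to the mutant, at 0.312 ± 0.352 rpm in the wild type and 23.8 and 101 in rdr2 replicates 1 and 2 (log2 fold change 8.03, SE 1.02, edgeR adjusted p = 0.00181).

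Most listed miRNAs stood higher in rpm in rdr2, 32 of 37 against 5 lower, with a median log2 fold change of 1.26. The lower share of 24-nt reads would raise all other reads by only 0.071 on the log2 scale, while the smallest change among the miRNAs that rose was 1.27 (SE 0.45), which argues against that loss as the whole cause. A higher ratio of miRNAs to fragments of other RNA in the rdr2 libraries may account for part of the rise; cytosolic rRNA fragments moved by -0.0544, and without a spike-in such a common factor cannot be told apart from a change in the plant. Differences among miRNAs argue against it as the whole cause, since miR157a moved by 3.98 (SE 0.51) and miR158a by -1.29 (SE 0.60) in rpm, and 17 miRNAs passed the threshold relative to their sum, 11 with TMM factors within the list. In the fit of all tags at the same scale 0 passed over the list, with the fold changes kept (1.84 for miR157a and -3.48 for miR158a) and the SE larger (0.98 and 1.14 against 0.35 and 0.46). The SE was computed from the test statistic, so it gives no reason for the absence of calls. The 17 and 11 calls over the list thus depend on fitting the listed miRNAs alone.

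The mitochondrial rRNA fragments were lower in rdr2 for both rRNAs, at 208 ± 97.0 against 710 ± 234 rpm for the 5S rRNA and 127 ± 11.4 against 648 ± 159 for the part of the 18S rRNA listed, without overlap in fragments of 18 to 24 nt (5.57-fold lower over both) and with overlap in those of 28 to 30 nt. Fragments of the listed plastid rRNAs moved by 0.30 and those of the listed cytosolic rRNAs by -0.0544 on the log2 scale, both with overlap. These values argue against fewer fragments of every listed rRNA as the cause. Fragments of rRNAs not listed were not measured, so a loss of rRNA fragments in general was not tested. Fragments cut from double strands made by RDR2 would come from both strands, and at least 99.98% of the matched reads were of the sense strand. A base difference in the rRNA of the mutant would lower only the tags across it; both 40-nt ends of the 5S rRNA, which share no tag, were lower, the less changed by -1.43, which argues against it there. In the 18S rRNA the first window kept its level (-0.0391) and the last was lower by -1.14 without overlap; a 24-nt fragment between them, with 32.2% of the wild type reads, was 36.7-fold lower, so that 1 base under that fragment does not account for the last window, while more than 1 differing base cannot be told apart there. A difference in anther stage or in mitochondria between the genotypes was not tested and stays open.

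Wild type replicate 1 held 1666 tags with at least 20 reads that had none in the other 4 libraries, against 2, 2, 3 and 17 such tags in the others. Its greater depth is not the whole cause: thinned to 4785826 reads, it still had 2422 tags of at least 5 reads found nowhere else, against 1000 in rdr2 replicate 2, the next highest. RNA of another plant in that library is a candidate source. Reads matching rRNA of another plant group but not that of Brassica were at 465 rpm there. The next highest level was 113 rpm in rdr2 replicate 2, above wild type replicates 2 and 3 and rdr2 replicate 1. The tests required reads in at least 2 libraries, so tags found in 1 library alone did not enter them. Tags of another plant shared by wild type replicate 1 and rdr2 replicate 2 could have passed this filter, and they were not counted. The 1666 tags of at least 20 reads found in wild type replicate 1 alone held 0.311% of the reads of that library. Tags of that library with fewer reads were not counted in this share. Without wild type replicate 1, 909 of the 24-nt tags not contained in longer tags fell and 9 miRNAs rose. The rRNA sequences of the other plant group were written from general knowledge after the tags had been seen, so this match was not independent of the tags that prompted it.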
